A study of Mus musculus with 48 samples.

How the data were processed

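Messenger RNA was measured on Illumina mouse bead arrays in 48 libraries of bone-marrow derived macrophages from C57BL/6 mice: 4 treatments (untreated, poly(I:C), R848, both ligands) at 6 times, in 2 experiments. Per the labels, RNA was isolated with Qiagen RNeasy, labelled with the Illumina TotalPrep kit and hybridised to slides of 8 arrays, and the scans were read with GenomeStudio 2011.1. Each of the 6 slides holds 1 experiment, 2 adjacent times and all 4 treatments, so treatments were compared within slides and distant times between slides. The array's build and any background correction by the scanner software are not given in the sources used here.

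Per the file headers, the scanner tables hold, for each of 25697 probes, the mean raw signal intensity, a detection p-value and the number of beads. The deposited intensity values had not been background-subtracted or normalized, as their values show. The deposited detection p-value of a probe is the share of negative control probes brighter than it; its step of 0.0012531 implies 798 negative controls. The deposited numbers of beads (other values) were at least 4 for every probe and array. The authors' normalized table holds log2 signals of 19692 probes after quantile normalization, per the labels and as the identical sorted columns show; the authors' series table held the same values, and their correlation with the log2 raw intensity was 0.9887 or more on every array.

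The raw intensities were background-corrected and quantile normalized with the negative controls inferred from the detection p-values, by the neqc function of limma 3.58.1 in R 4.3.3 with an offset of 16. Of the probes in the authors' table, 18613 carry 1 gene symbol in the probe table and stand for 13417 genes; 1079 probes with no single symbol were left out of the comparisons. Each gene was represented by its brightest probe. A gene was tested when its probe had a detection p under 0.01 in both libraries of at least 1 group, which left 7695 genes. The symbols were those of the probe table; 0 of them needed an update.

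One linear model with a mean for each of the 24 groups was fitted to all genes with limma (24 residual degrees of freedom, 2.92 prior degrees of freedom from empirical Bayes moderation). Adjusted p-values are Benjamini-Hochberg values over the 7695 genes within a comparison. A gene was called at an adjusted p under 0.05 and a change of at least 2-fold. The number of genes in a comparison over all times comes from a moderated F-test over the 6 times, with the fold required at 1 or more times; numbers at single times and in each direction come from the tests of single times. The comparisons were each ligand and both ligands against untreated, both ligands against each ligand, R848 against poly(I:C), the interaction on the log2 scale, the responses at 12 h against those at 2 h, the change from 2 to 12 h between treatments, and untreated cells at 12 h against 0.5 h.

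For additivity, the expected signal of both ligands was computed within each experiment and time as the signal under poly(I:C) plus that under R848 minus that of untreated cells, on the scale of the signal; an expectation below 0 was set to 0 before the offset of 16 was added. The log2 ratio of observed to expected was tested with limma on its 12 values per gene (6 residual and 2.91 prior degrees of freedom), and a call needed a departure of 1.5-fold. A gene was called above the sum only where it was called higher under both ligands than untreated, and below it only where it was called higher under a ligand. For named genes with a group at background in both libraries, the departure, or a difference that spans 4 groups, is given as a bound, with that group's signal at 0 or at the library's floor, whichever brings the value closer to 0.

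The library number in the labels is the experiment number. Across genes, the differences between the experiments correlated between groups in all 276 pairs of groups (Pearson r from 0.161 to 0.86, median 0.727; genes are not independent replicates), so the numbers pair the samples across treatments and times. The experiment was therefore also fitted as a block among the alternatives, and a blocked value stands beside a result where it changes a call or moves a count by over 1.5 times.

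Lists of genes were tested with limma's camera function, which compares a list with all other genes, with its preset correlation of 0.01 between genes. With 26 lists of 3 or more measured members at 6 times for poly(I:C), R848, both ligands and additivity, there were 624 tests with 1 common adjustment; 209 passed, and 156 passed with an estimated correlation, all of them among the 209. The lists cover immediate-early genes, NF-kB feedback, cytokines, chemokines, interferons, interferon-stimulated genes, interferon-induced GTPases, MHC class I and II, co-stimulation, the TLR pathway, IRF and STAT factors, inflammatory enzymes, cell death, SOCS and DUSP feedback, cholesterol synthesis and efflux, glycolysis, the TCA cycle with oxidative phosphorylation, the cell cycle, macrophage identity, lysosome, stress response, ribosomal proteins, housekeeping genes and markers of T cells, B cells, NK cells, neutrophils, dendritic, stromal and erythroid cells, mast cells and basophils, and megakaryocytes. Their members were written from general knowledge, not from these samples, and 1 gene may stand in several lists.

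Where both libraries of a group had a detection p of 0.01 or more, the fold is a lower bound: the mean log2 signal of the other group against the mean over the 2 libraries of the higher of the gene's signal and the library's floor, the lowest signal of any probe above background. Among 184 list tests of 2 groups that passed, 97 held a gene at such a bound; setting these at their bounds shifted the list median by at most 0.99 and changed the sign of 0 medians.

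Genes were named by a rule. It takes 34 indicator genes of macrophage activation, of which 31 were measured, the 5 largest rises and falls called in the same direction in both experiments for each ligand at 2 and 12 h and for the other comparisons at 12 h, up to 4 members of each described list, and the 10 genes furthest above and 5 furthest below additivity. Indicator genes named here without a called change are given with their values. Of the indicators, Csf2 was above background in 1 library and was not tested, and the others not measured had no named probe. Where a named gene had further probes above background in both libraries of at least 1 group, each of these moved in the same direction as the brightest. This was read at the time of the gene's largest change under both ligands. The size could differ, so a named change is that of the brightest probe. At 12 h of both ligands Mmp13 read 5.81 on its brightest probe and 4.95 and 1.07 on others. Adssl1 read -4.87 against -4.63 and -1.62, and Hp 4.76 against 4.85 and 4.73.

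The choices of tests, thresholds, filters, lists, named-gene rule and 20 alternatives were made before the data were examined. The alternatives were quantile normalization of the raw signal, median centring, the authors' table, their series table (which held the same values and was not fitted again), 3 other detection filters, experiment or slide as a block, slide as a random block, every probe, only the libraries of the times compared, an intensity trend with robust spread, no minimum fold, an adjusted p under 0.01, leaving out each library, an offset of 64, the larger single ligand or a 2-fold minimum for additivity, and an estimated correlation for lists. After seeing the data, 3 were added: leaving out the 3 libraries that stand apart, the experiment block with array quality weights, and the experiment block without the 3 libraries. Unless a block is named, fits of groups that leave out a library hold no term for the experiment. The remaining library of that group is then set against means over both experiments, so such values also carry the difference between the experiments.

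The tests were tested on simulated data with 2 libraries per group and 7695 genes. Of 50 genes changed by 2-fold at 4 h of poly(I:C), 40% were recovered at that time, and of 50 changed by 4-fold 82%, with 0 false calls; the F-test over all times recovered 22% and 56%. Of 50 genes set at 4-fold above the sum, 72% were recovered, and of 50 at 2-fold 6%. Of 100 genes set at 2-fold below the sum, 12% were recovered. A list of 20 genes raised by 1.5-fold was recovered. Probe sequences, probe positions and the arrays' raw images were not used here.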

Results

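The data are mRNA levels measured on Illumina bead arrays in macrophages grown from the bone marrow of C57BL/6 mice. The cells were left untreated or were given poly(I:C), R848 or both ligands together. Poly(I:C) is a synthetic double-stranded RNA sensed by Toll-like receptor 3 (TLR3), and R848 is a small-molecule ligand of TLR7 and TLR8. They were harvested at 0.5, 1, 2, 4, 8 and 12 h. Each of the 24 combinations of treatment and time was measured in 2 libraries, 1 from each of 2 experiments, which gives 48 arrays. Ligand doses are not given in the sources used here. TLR3 signals through the adaptor TRIF and TLR7 through the adaptor MyD88. The design asks how macrophages respond to each ligand alone and whether the response to both differs from the sum of the responses to each. Which receptor or adaptor carried a response was not tested.

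Mean raw signal per array ran from 307.8 to 388.1 in experiment 1 and from 434.3 to 589.7 in experiment 2. Between 30.6% and 39.5% of the probes were above background on an array of experiment 1, and between 38.8% and 44.6% on an array of experiment 2. The tests covered 7695 genes, named by the symbols of the array's probe table and each represented by 1 probe; probe positions on the genome were not used here. Every difference below is between the means of 2 libraries in each of the groups compared, on the log2 scale, with the standard error (SE) of the fit after the ± sign. Genes are said to have risen or fallen where limma's moderated test gave an adjusted p under 0.05 and a change of 2-fold or more. Where a gene was at background in both libraries of a group, the change is given as a lower bound ("at least"). The p-values measure the spread between the 2 libraries of a group, pooled over the groups. That spread holds the difference between the experiments, for which the main fit has no term. The number of arrays limits the precision of every value.

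The main axis of variation among the 48 libraries followed treatment and time. The first principal component held 40.9% of the variance, and the groups of treatment and time accounted for a share of 0.993 of it. The second component held 18.2%, and experiment accounted for a share of 0.697 of it. Across the tested genes, the SD between the 2 libraries of a group had a median of 0.305 log2 units, and the correlation between them ran from 0.856 to 0.980. The lowest values belonged to 3 libraries of experiment 1 that stood apart on the second component. In the library of both ligands at 2 h, 490 genes (6.4% of those tested) had lost signal that its partner from experiment 2 kept; in the R848 library at 12 h it was 239 genes and in the poly(I:C) library at 8 h 131 genes. In the other 21 groups the highest count was 2. Hspa8, a chaperone gene expressed in all cells, read 4.31 in the first of these libraries and 12.41 in its partner, and Eif5a, a translation factor gene, read 4.33 and 11.04. A count without these 3 libraries is given where it differs by over 1.5 times.

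**Figure D1:**
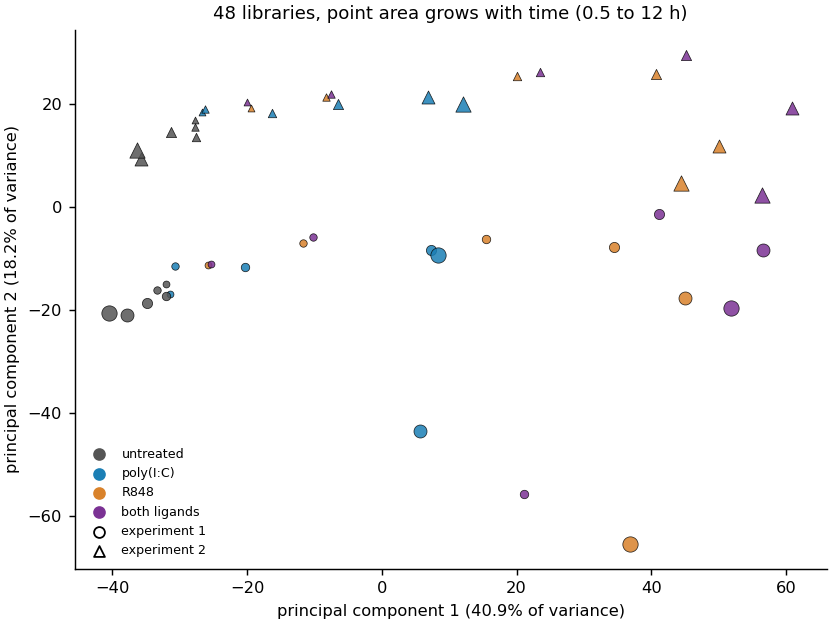
Principal components of the log2 normalized signal of 7695 genes in 48 libraries, component 1 (40.9% of the variance) against component 2 (18.2%), in arbitrary units; each point is a library, colour gives the treatment, and circles and triangles mark experiments 1 and 2. Libraries spread along component 1 by treatment and time, and 3 libraries of experiment 1 lie far from the rest on component 2.

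Poly(I:C) against untreated cells shows the response to the TLR3 ligand alone. After 12 h, Ch25h, which makes 25-hydroxycholesterol, was 76.3-fold higher (log2 difference 6.25 ± 0.36, adjusted p = 3e-13), and Cxcl10, an interferon-induced chemokine, was 41.1-fold higher (5.36 ± 0.20, adjusted p = 2.5e-17). Ptges, a prostaglandin E synthase gene, was at least 39.5-fold higher. Clec4e, a receptor for mycobacterial glycolipids, rose by 4.69 ± 0.22 and Ccl2, which attracts monocytes, by 4.41 ± 0.34. The largest falls at 12 h were in St6gal1, a sialyltransferase gene (-4.32 ± 0.18, adjusted p = 6e-16), Slc46a3, a lysosomal transporter gene (-3.96 ± 0.27), Cxcr4, the receptor of the chemokine CXCL12 (-3.91 ± 0.31), and Cnr2, a cannabinoid receptor gene (-3.40 ± 0.16). Fam214a was at least 7.71-fold lower.

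Single genes passed under poly(I:C) from 2 h on. At 0.5 and 1 h limma called 0 genes, with 35 and 57 genes at an unadjusted p under 0.05. As lists, chemokine genes (median 0.32, adjusted p = 2.9e-10, and 8.9e-05 with an estimated correlation), immediate-early genes (0.29, 9.1e-07 and 0.01) and cytokine genes (0.16, or 0.11 at the bounds, 7.2e-05 and 0.1) had moved up by 1 h. SOCS and DUSP feedback genes (0.10, 0.004 and 0.13) also passed at 1 h, but not without the poly(I:C) library of experiment 2 (0.02) or the untreated one of experiment 1 (0.04). Calls of glycolysis genes at 1 h (-0.11, 0.045) and of TCA cycle genes at 0.5 h (-0.12, 0.018) each ended without any 1 of the 4 libraries compared, at -0.20 to -0.01 and -0.15 to -0.08. At 2 h Socs3, an inhibitor of cytokine signalling, rose by 3.58 ± 0.45, Ifnb1, which encodes interferon beta, by 3.47 ± 0.27 (adjusted p = 3.4e-09) and Tnf by 2.56 ± 0.32. Ifnb1 was still 4.07 ± 0.27 higher at 4 h and 4.22 ± 0.27 higher at 12 h. Cxcl2 (3.67 ± 0.74) and Il1b (2.66 ± 0.53) were also called higher at 2 h. Each call ended without any 1 of the 4 libraries compared, at 3.31 to 4.02 for Cxcl2 and 2.61 to 2.72 for Il1b. The falls called at 2 h were in 4 genes. Frat2 (-1.36 ± 0.22) lost its call, at -1.19, without the untreated library of experiment 1. Lpar6, Enc1 and Gpr146 lay between -1.13 and -1.05 and lost their calls without any 1 of the 4 libraries, at values between -1.30 and -0.83. After quantile normalization of the raw signal 0 genes fell and 20 rose at 2 h, against 4 and 30, and with each array centred on its median 2 fell and 11 rose. Without 1 library the count of genes that rose was 16 or 18 (poly(I:C), experiments 1 and 2) or 16 (untreated, experiment 2). By 12 h 431 genes were higher and 502 lower, a share of 46.2% higher, against 54.6% after quantile normalization and 36.6% with median centring.

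At 12 h of poly(I:C), part of the genes in 4 lists of the interferon response and antigen presentation rose. Of 37 measured interferon-stimulated genes, 10 rose and 0 fell (11 rose adjusted over the list alone), with a list median of 0.92 (adjusted p = 2.8e-12, and adjusted p = 5.3e-06 with an estimated correlation). Mx2, an antiviral GTPase gene, rose by 2.72 ± 0.39 and Oasl1 by 2.69 ± 0.20. Of 10 interferon-induced GTPase genes, which act against intracellular pathogens, 6 rose (8 adjusted over the list alone) with a median of 1.83 (adjusted p = 5.4e-10, and 0.00013 with an estimated correlation): Gbp5 by 4.25 ± 0.63, Tgtp1 by 2.90 ± 0.28 and Gbp2 by 2.04 ± 0.13. Interferon genes themselves had a median of 0.27 over 4 members, of which Ifnb1 rose (adjusted p = 0.049, and adjusted p = 0.12 with an estimated correlation). This list's call ended with the experiment as a block and, at a median of 0.19, without the untreated 12 h library of experiment 2. In antigen presentation on MHC class I, 3 of 12 genes rose (3 adjusted over the list alone), with a median of 0.82 (adjusted p = 0.00043, and 0.039 with an estimated correlation). Tap1, a peptide transporter gene, rose by 1.62 ± 0.31.

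Inflammatory gene groups rose in the same cells. Of 11 chemokine genes 7 rose at 12 h of poly(I:C) (8 adjusted over the list alone; median 1.86, adjusted p = 1.8e-11, and 4.6e-05 with an estimated correlation), Ccl7 by 4.21 ± 0.48. Of 21 cytokine genes 9 rose (10 adjusted over the list alone; median 0.97, or 0.84 with genes at background set at their bounds, adjusted p = 3.1e-07, and 0.033 with an estimated correlation), Tnf by 3.89 ± 0.32, Il27 by 3.20 ± 0.52 and Il1rn, which encodes the interleukin 1 receptor antagonist, by 2.82 ± 0.29. Feedback genes of the NF-kB pathway rose in 10 of 17 cases (11 adjusted over the list alone; median 1.29, adjusted p = 1.6e-08, and 0.017 with an estimated correlation), with Traf1 at 4.11 ± 0.32 and Tnfaip3, a brake on NF-kB, at 2.74 ± 0.40. Among 13 inflammatory enzymes and effectors 9 rose (9 adjusted over the list alone; median 1.42, adjusted p = 1.2e-12, and 0.00018 with an estimated correlation). Hdc, which makes histamine, rose by 4.11 ± 0.27, and Nos2, the inducible nitric oxide synthase gene, was at least 4.85-fold higher. Macrophage identity genes had a median of -0.38, and 5 of 18 fell (5 adjusted over the list alone; adjusted p = 0.012, and adjusted p = 0.2 with an estimated correlation), among them the mannose receptor gene Mrc1 (-2.36 ± 0.17) and Fcgr3 (-1.52 ± 0.21). With each array centred on its median the list's median was -0.19 and its call ended.

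Over all times, 997 genes (13%) were called for poly(I:C) against untreated by limma's F-test, and tests of single times called 553 higher and 622 lower at 1 or more times. Leaving out any 1 of the 48 libraries left between 905 and 1149 genes.

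**Figure D2:**
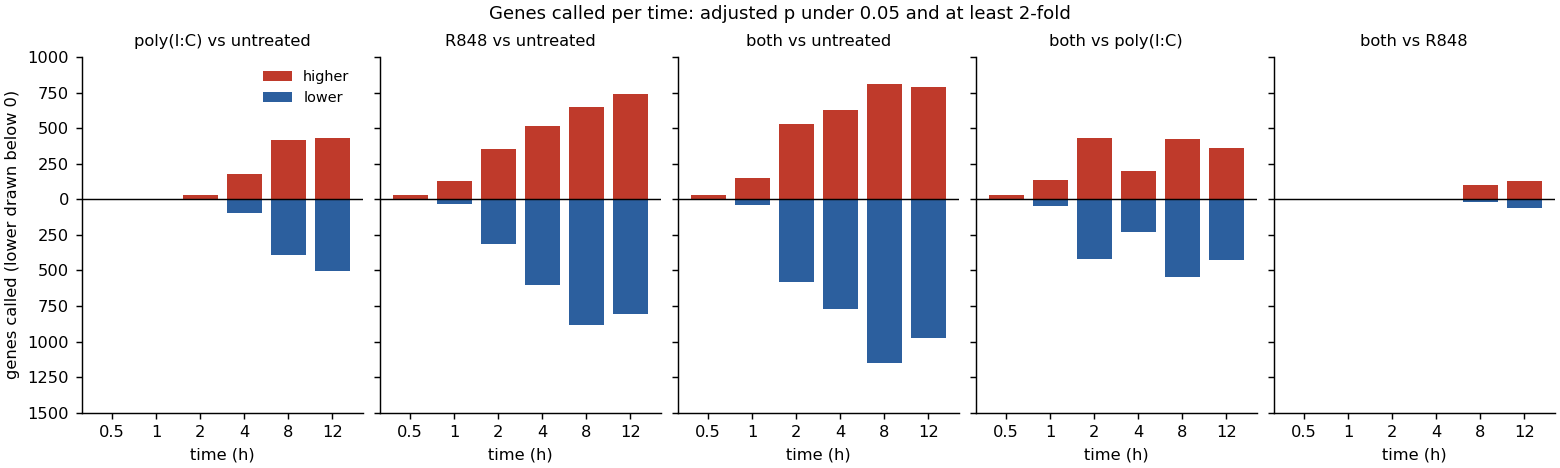
Number of genes called higher (bars above 0) and lower (bars below 0) at each time in 5 comparisons of 2 libraries against 2. Poly(I:C) alone has no bar at 0.5 and 1 h and reaches 431 genes higher and 502 lower at 12 h, and R848 alone reaches 740 and 806.

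R848 against untreated cells shows the response to the TLR7 and TLR8 ligand alone, and it began within 0.5 h. By then Egr1, an immediate-early transcription factor gene, was 52.8-fold higher (5.72 ± 0.29, adjusted p = 1.6e-13), Dusp2, a phosphatase gene that limits MAP kinases, was up by 5.32 ± 0.68, Cxcl2 by 5.98 ± 0.74, Tnf by 3.64 ± 0.32 and Il10, an anti-inflammatory cytokine gene, by 3.23 ± 0.22. Ifnb1 rose by 3.16 ± 0.27 at 1 h and by 1.56 ± 0.27 at 4 h, and at 12 h it was at background in both R848 libraries. Fos, another immediate-early gene, differed by 1.54 ± 0.51 at 0.5 h and passed the test only with the experiment as a block. Of 15 immediate-early genes 8 rose and 2 fell at 2 h (median 1.57, adjusted p = 3.4e-08, and 0.0045 with an estimated correlation).

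At 2 h of R848 the largest rises were in Il1a, which encodes interleukin 1 alpha (7.58 ± 0.88, adjusted p = 2.6e-07), the neutrophil chemoattractant genes Cxcl1 (7.39 ± 0.85) and Cxcl2 (6.83 ± 0.74) and Ch25h (5.58 ± 0.36). Edn1, the endothelin 1 gene, was at least 43.8-fold higher. The lysophosphatidic acid receptor gene Lpar6 fell most (-4.29 ± 0.26, adjusted p = 4.5e-12), followed by Fam78a (-3.48 ± 0.29), Hhex, a homeobox transcription factor gene (-3.35 ± 0.29), and Arrdc3 (-3.32 ± 0.36). Cnr2 was at least 9.5-fold lower. NF-kB feedback genes rose in 12 of 17 cases at 2 h (14 adjusted over the list alone; median 1.96, adjusted p = 4.4e-19, and 0.00049 with an estimated correlation), with Rel at 3.58 ± 0.37 and Traf1 at 3.43 ± 0.32. Of 14 cholesterol synthesis genes 1 rose at 2 h, Cyp51 by 1.48 ± 0.24, and the list's median was 0.55 (adjusted p = 0.0078, and 0.017 with an estimated correlation). At 4 h 5 of 18 cell cycle genes fell, among them Ccnd1, the cyclin D1 gene (-2.55 ± 0.29), and Cdt1, a DNA replication licensing gene (-1.19 ± 0.17). The list's median was -0.61 (adjusted p = 0.01, and 0.018 with an estimated correlation), and its call ended, at -0.66, without the R848 4 h library of experiment 1.

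After 12 h of R848, Lcn2, which encodes the iron-chelator carrier lipocalin 2, was 157-fold higher (7.30 ± 0.43, adjusted p = 1.1e-13). Il1a was higher by 7.19 ± 0.88 and Cxcl2 by 6.97 ± 0.74, and Ptges and Serpinb2, a protease inhibitor gene, were at least 109-fold and at least 59.3-fold higher. Slc46a3 fell by 6.55 ± 0.27 (adjusted p = 1.2e-16), Zfp36l1, which encodes an mRNA decay factor, by 5.31 ± 0.23, Slc40a1, the iron exporter gene, by 5.01 ± 0.28 and Ccnd1 by 4.88 ± 0.29. Cxcr4 was at least 27.5-fold lower. Cytokine genes rose in 13 of 21 cases and fell in 2 (14 and 2 adjusted over the list alone; median 1.80, or 1.58 at the bounds, adjusted p = 1.1e-05, and adjusted p = 0.069 with an estimated correlation). Tnf rose by 5.06 ± 0.32, Il1b by 4.92 ± 0.53 and Il10 by 4.23 ± 0.22, and Il12a was at least 10.6-fold higher. Chemokine genes rose in 8 of 11 cases (median 1.82, adjusted p = 3.7e-05, and 0.0034 with an estimated correlation). Inflammatory enzymes rose in 9 of 13 cases (10 adjusted over the list alone; median 2.02, adjusted p = 7.8e-11, and 0.00038 with an estimated correlation), with the arginine transporter gene Slc7a2 at least 44.8-fold higher. NF-kB feedback genes rose in 11 of 17 cases (14 adjusted over the list alone; median 1.80, adjusted p = 3.1e-08, and 0.019 with an estimated correlation).

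Other lists at 12 h of R848 held falls in part of their members. Of 18 macrophage identity genes 7 fell and 0 rose (8 fell adjusted over the list alone; median -1.01, adjusted p = 8.4e-05, and 0.045 with an estimated correlation). Among them were Mertk, a receptor for the uptake of dying cells (-4.62 ± 0.21), Mrc1 (-3.91 ± 0.17) and Trem2 (-1.97 ± 0.16). Of 8 MHC class II genes 4 fell (median -0.86, adjusted p = 0.0083, and adjusted p = 0.18 with an estimated correlation). H2-DMa was at -3.05 ± 0.29 and H2-DMb1 at -1.61 ± 0.19, and Ciita, the master regulator of the class, was at least 2.07-fold lower. Interferon-stimulated genes had a median of -0.46, and 6 of 37 fell and 0 rose (adjusted p = 0.029, and adjusted p = 0.054 with an estimated correlation), with Ifit2 at -2.91 ± 0.19. This list's call ended at -0.27 without the R848 12 h library of experiment 1, at -0.17 without the untreated 12 h library of experiment 2 and at -0.32 with each array centred on its median. Lysosome genes fell in 3 of 16 cases (median -0.54, adjusted p = 0.03, and 0.042 with an estimated correlation). That call ended at -0.40 and -0.44 without the same libraries and at -0.31 with median centring. Of 12 glycolysis genes 6 rose and 1 fell (median 1.04, adjusted p = 0.00068, and adjusted p = 0.088 with an estimated correlation). The glucose transporter gene Slc2a1 rose by 1.97 ± 0.17, and the lactate exporter gene Slc16a3 was at least 3.42-fold higher.

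For R848 against untreated, 2206 genes (28.7%) were called over all times, 1070 higher and 1382 lower at 1 or more times, 15 of them in both directions. At 12 h 740 genes were higher and 806 lower. Leaving out any 1 library left between 2098 and 2472 genes. The share of higher genes among those called moved with the scaling at earlier times. At 1 h it was 78.8%, against 94.3% after quantile normalization of the raw signal. At 2 h it was 53%, against 37.2% with median centring and 74.2% after quantile normalization, and at 4 h 46.1%, against 35.1% with median centring and 55.2% after quantile normalization.

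**Figure D3:**
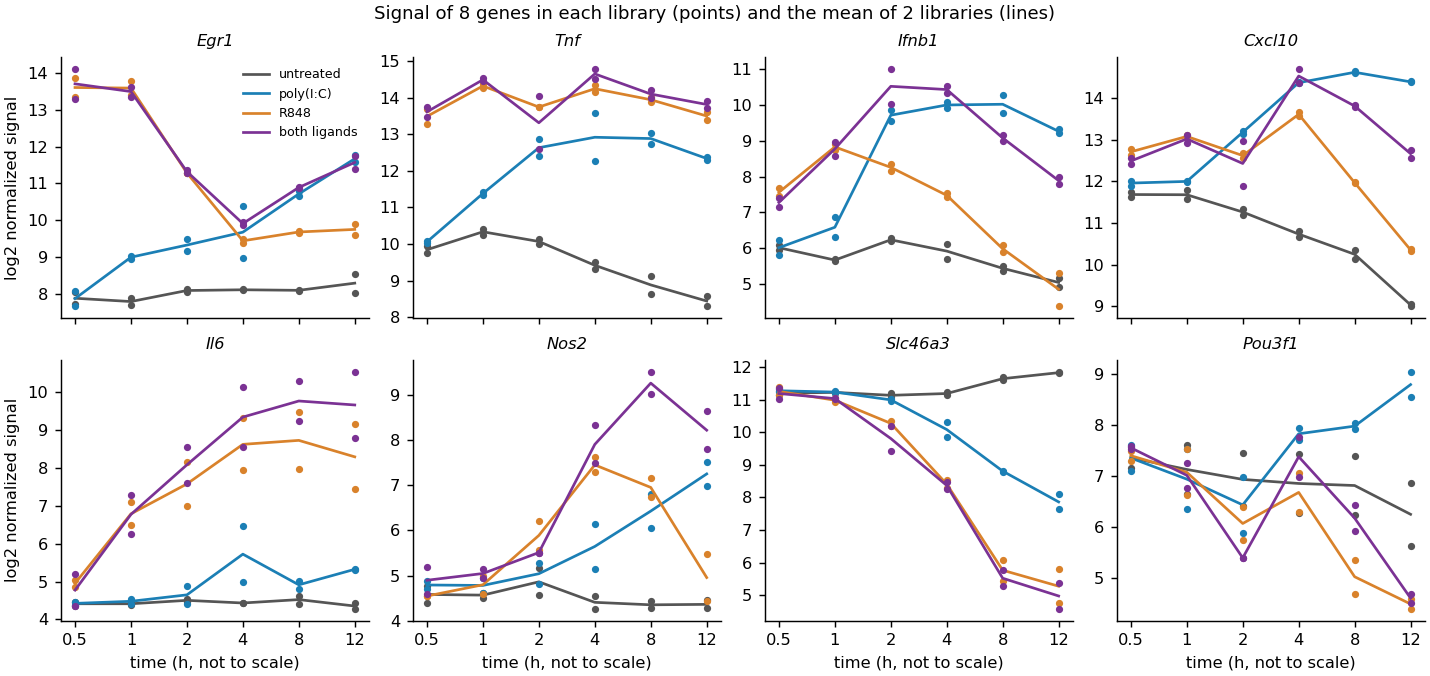
Log2 normalized signal of 8 genes against time after ligand (h, spaced evenly and not to scale); points are single libraries, lines join the means of 2 libraries, and colour gives the treatment. Egr1 is up by 0.5 h under R848 (5.72), Ifnb1 is still up at 12 h under poly(I:C) (4.22) and is at background under R848 by then, and Slc46a3 falls under each ligand.

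Both ligands against untreated cells shows the combined response. At 12 h Il1a was 292-fold higher (8.19 ± 0.88, adjusted p = 1.4e-08) and Lcn2 265-fold higher (8.05 ± 0.43, adjusted p = 9.5e-15). Cxcl2 rose by 7.38 ± 0.74, and Ptges and Serpinb2 were at least 177-fold and at least 142-fold higher. Il10 rose by 5.18 ± 0.22, Il27 by 5.75 ± 0.52 and Ifnb1 by 2.84 ± 0.27. Il6 was at least 25.8-fold and Nos2 at least 9.5-fold higher. Slc46a3 was at least 101-fold and Cxcr4 at least 30.2-fold lower. Ccnd1 (-5.80 ± 0.29), Sesn1, a stress-inducible regulator of growth (-5.23 ± 0.23), and Tsc22d3, a glucocorticoid-induced gene (-5.16 ± 0.31), fell most among the other named genes.

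The 12 h response to both ligands raised 14 of 21 cytokine genes and lowered 1 (median 3.82, or 3.27 at the bounds, adjusted p = 2.1e-10, and 0.0094 with an estimated correlation). Chemokine genes rose in 8 of 11 cases (median 3.63, adjusted p = 9.8e-07, and 0.00083 with an estimated correlation). Inflammatory enzymes rose in 12 of 13 cases (median 3.15, or 2.74 at the bounds, adjusted p = 7.6e-14, and 1e-04 with an estimated correlation), with Slc7a2 at least 82.1-fold higher and Ch25h up by 5.46 ± 0.36. NF-kB feedback genes rose in 15 of 17 cases (median 1.96, adjusted p = 5.4e-09, and 0.014 with an estimated correlation). Glycolysis genes rose in 6 of 12 cases (median 1.21, adjusted p = 3e-05, and 0.037 with an estimated correlation), with Slc2a1 at 2.56 ± 0.17 and the phosphofructokinase gene Pfkl at 1.80 ± 0.22. Interferon-induced GTPase genes rose in 5 of 10 cases (median 1.34, adjusted p = 0.0061, and 0.043 with an estimated correlation). Interferon-stimulated genes had a median of 0.31, with 6 of 37 higher and 1 lower (adjusted p = 0.081). The list passed the test without the 12 h library of both ligands of experiment 1 or the untreated one of experiment 2, and with median centring. Lysosome genes fell in 5 of 16 cases (median -0.77, adjusted p = 0.019, and 0.03 with an estimated correlation), with Hexa at -1.57 ± 0.22 and Gusb at -1.33 ± 0.21. The list's call ended at -0.54 without the untreated 12 h library of experiment 2 and at -0.45 with median centring. Macrophage identity genes fell in 6 of 18 cases (7 adjusted over the list alone; median -0.77, adjusted p = 0.0018, and adjusted p = 0.11 with an estimated correlation), with Mertk at -4.01 ± 0.21 and the M-CSF receptor gene Csf1r at -1.79 ± 0.23. MHC class II genes fell in 4 of 8 cases (median -1.04, adjusted p = 0.013, and adjusted p = 0.21 with an estimated correlation).

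At 2 h of both ligands Cxcl1 rose by 7.39 ± 0.85, Il1a by 6.79 ± 0.88, Cxcl2 by 6.52 ± 0.74 and Ch25h by 5.59 ± 0.36, and Edn1 was at least 39.4-fold higher. Lpar6 (-3.64 ± 0.26) and Cxcr4 (-3.46 ± 0.31) fell, and Cnr2 was at least 7.64-fold lower. The other large falls at 2 h, in Gm5560 (-3.42 ± 0.94) and Rps2, a ribosomal protein gene (-3.39 ± 0.85), came from the library of experiment 1 that stood apart. Without it they were -0.21 and -0.47 and no longer called, without its partner -6.62 and -6.30, and Gm5560 also lost its call, at -3.26, without the untreated library of experiment 2. Over all times 2679 genes (34.8%) were called for both ligands, 1192 higher and 1812 lower at 1 or more times, 19 of them in both directions. Leaving out any 1 library left between 2582 and 3472. At 12 h 787 genes were higher and 973 lower. The share of higher genes among those called was 47.6% at 2 h, against 25.2% with median centring, 44.7% at 4 h, against 29.7%, and 41.3% at 8 h, against 27.3%. After quantile normalization it was 54% at 2 h and 54.4% at 4 h. At 1 h it was 78.3%, against 93.4% after quantile normalization.

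R848 against poly(I:C) asks how the ligands differ. At 12 h Lcn2 was higher under R848 by 6.11 ± 0.43 (adjusted p = 1.1e-11), Il1a by 4.85 ± 0.88, Cxcl1 by 4.66 ± 0.85 and Gja1, a gap junction gene, by 4.54 ± 0.27. Shisa3 was at least 16.6-fold higher. Ccnd1 (-5.76 ± 0.29, adjusted p = 1.8e-14) and BC147527 (-4.19 ± 0.23) were lower under R848, while Ifnb1 was at least 15.6-fold and Pou3f1, a transcription factor gene, at least 11.2-fold lower. Ifit3b, an interferon-stimulated gene, was also lower (-5.70 ± 1.33), a call that ended at -3.62 without the R848 12 h library of experiment 1. Over all times 1465 genes (19%) differed (831 higher and 967 lower under R848 at 1 or more times, 44 in both directions; between 1368 and 1889 with 1 library left out). At 12 h 458 genes were higher and 511 lower under R848. Without the R848 library of experiment 1 there were 266 higher, and without that of experiment 2 there were 951 higher and 783 lower. The share of higher genes at 12 h was 47.3%, against 37.2% after quantile normalization and 57.1% with median centring, so which direction holds more genes depends on the scaling. At 4 h it was 44.6%, against 65% and 37.2%.

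At 12 h 229 genes rose under both poly(I:C) and R848, of 431 and 740 in the separate comparisons, where independent lists would share 41.4. In the same way 339 genes fell under both, of 502 and 806 (52.6 for independent lists), and 21 genes rose under poly(I:C) and fell under R848, with 4 the other way. Both comparisons use the same untreated libraries, which were not divided between the ligands, so part of the excess may come from them. In 50 simulations of unchanged groups with shared controls the mean number of shared calls was 0, which leaves open what the shared controls add among genes that change. Of the genes called for both ligands at 12 h, 182 higher and 256 lower ones were called in the same direction under neither ligand alone. A missing call does not show that a ligand alone left a gene unchanged. Direct tests over all genes at 12 h called 126 higher and 61 lower under both ligands than under R848. Against poly(I:C) they called 362 and 427.

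Both ligands against poly(I:C) shows what R848 added. At 12 h Lcn2 was higher by 6.86 ± 0.43 (adjusted p = 1.6e-12), Il1a by 5.84 ± 0.88, Cxcl1 by 5.28 ± 0.85 and Il6, an acute-phase cytokine gene, by 4.34 ± 0.63. The cytokine gene Il19 was at least 40.7-fold and Shisa3 at least 19.8-fold higher. Ccnd1 (-6.67 ± 0.29, adjusted p = 1.4e-15), Plau, the urokinase gene (-4.15 ± 0.41), Cd180, a TLR4-related receptor gene (-3.45 ± 0.28), BC147527 (-3.32 ± 0.23) and Cxcl10 (-1.73 ± 0.20) were lower. Pou3f1 was at least 12.3-fold lower. Over all times 1603 genes (20.8%) were called, 849 higher and 1154 lower at 1 or more times, 35 in both directions. The count was 2574 without the 2 h library of both ligands of experiment 2, the partner of the library that stood apart. At 12 h 362 genes were higher and 427 lower, a share of 45.9% higher, against 58.5% with median centring. At 2, 4 and 8 h the share was 50.6%, 46.4% and 43.7%, against 37.9%, 26.3% and 19.6% with median centring and 54.7%, 65.5% and 54.7% after quantile normalization.

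Both ligands against R848 shows what poly(I:C) added. At 12 h Il19 was higher by 3.69 ± 0.28 (adjusted p = 8.3e-10), Nos2 by 3.27 ± 0.37, Inhba, which encodes an activin subunit, by 3.26 ± 0.36, Slamf1, a receptor of immune cells, by 3.25 ± 0.25 and Cxcl10 by 2.31 ± 0.20. Ifnb1 was at least 6-fold higher. Sesn1 (-2.12 ± 0.23, adjusted p = 5.1e-07), Tspan32 (-2.02 ± 0.28), Scamp5 (-2.02 ± 0.21) and Pim2, a kinase gene (-1.98 ± 0.22), were lower. Epb41l1 was at least 2.74-fold lower, a call that ended at -1.80 without the 12 h library of both ligands of experiment 1 and at -1.36 without the R848 one. Tnf (0.31 ± 0.32, adjusted p = 0.66) and Il6 (1.37 ± 0.63, adjusted p = 0.23) did not pass the test. Over all times 188 genes (2.44%) were called, 165 higher and 66 lower at 1 or more times. At 8 h 101 genes were higher and 17 lower, against 19 and 29 with median centring, 50 and 4 after quantile normalization and 55 and 4 with the authors' normalized values. The higher count at 8 h was 62 without the library of both ligands of experiment 1, and the lower count was 5 without the R848 library of experiment 1 and 8 without that of both ligands of experiment 2. At 12 h the share of higher genes was 67.4%, against 69.2% with median centring and 87.1% after quantile normalization. At 0.5 and 1 h limma called 0 genes, with 115 and 41 at an unadjusted p under 0.05. With the experiment as a block the count was 338. Without the 2 h library of both ligands of experiment 2 it was 1238 and without the R848 12 h library of experiment 2 it was 424.

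Additivity asks whether the signal under both ligands equalled the sum of the ligands' separate increases over untreated, on the scale of the signal itself. Where a group was at background in both libraries, its signal was set at the bound that brings the departure closest to 0. At 12 h Il19 was at least 11-fold above the sum (adjusted p = 0.00053). Its mean log2 signal was 6.80 under R848 and 10.49 under both ligands and was at background in untreated cells and under poly(I:C). Slamf1 was at least 7.03-fold and Inhba at least 4.59-fold above the sum, and Scarf2, a scavenger receptor gene, was above it by 2.39 ± 0.28 on the log2 scale. Pou3f1, at background under R848 and both ligands, was at least 10.6-fold below the sum. Below it lay also Plau (-3.87 ± 0.49), Gca (-3.20 ± 0.31), Slamf8 (-3.05 ± 0.20, adjusted p = 8.9e-06) and BC147527 (-2.95 ± 0.32). Slamf8 read 7.64 in untreated cells, 10.51 under poly(I:C), 6.68 under R848 and 7.36 under both.

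Other genes above the sum depended on the floor or on single libraries. The sum lay at the floor for Gab1, a signalling adaptor gene (5.63 ± 0.25), on both arrays, with signals of 8.58, 6.62, 7.89 and 9.63 in untreated, poly(I:C), R848 and both. Without the 12 h library of both ligands of experiment 1 Gab1 was no longer called higher under both ligands. It lay at the floor also for Ifitm1, at background under each ligand alone and at least 3.62-fold above the sum. Satb1 and Csta2 were at background in untreated cells and under each ligand alone, so their sums rest on background signals, and they were at least 1.14-fold and at least 1.63-fold above the sum. Csf3, the G-CSF gene (at least 3.48-fold above), lost its call without any 12 h library of experiment 1. Arg2, an arginase gene (2.04 ± 0.38), lost its call, at 1.21, and Csta2 lost its call without any 12 h library of experiment 2.

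Among the genes chosen in advance as indicators, Cxcl10 (-1.78 ± 0.27), Il15 (-1.74 ± 0.18) and Tgtp1 (-1.55 ± 0.19) were below the sum at 12 h, and Ifnb1 was at least 2.53-fold below. Il6 was at least 2.37-fold above it (adjusted p = 0.015), a call that ended without any 1 of the 8 libraries at 12 h. Tnf (-0.19, adjusted p = 0.69), Il1b (0.14) and Cd40 (-0.07) did not pass the test. By list, interferon-stimulated genes had a median departure of -0.51, with 5 of 37 below the sum and 0 above (7 adjusted over the list alone; adjusted p = 0.00025, and adjusted p = 0.054 with an estimated correlation). Interferon-induced GTPase genes had -0.63, with 4 of 10 below (5 adjusted over the list alone; adjusted p = 0.0027, and adjusted p = 0.14 with an estimated correlation). Cytokine genes had 0.52, with 6 of 21 above and 1 below (7 and 2 adjusted over the list alone; adjusted p = 0.054). At 8 h their median was 0.61 with 6 above (adjusted p = 0.021, and adjusted p = 0.32 with an estimated correlation), which ended at 0.57 without any 8 h library of experiment 1.

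Additivity was tested at each time. At 12 h 39 genes were above the sum and 194 below, against 53 and 115 with median centring and 25 and 132 after quantile normalization. Over all times 49 genes were above and 227 below at 1 or more times. The count of genes above at 12 h was 23 without the untreated library of experiment 1, 24 without any other 12 h library of experiment 1 and 22 without the untreated library of experiment 2. The count below was 66 without the untreated, poly(I:C) or R848 library of experiment 1, 67 without that of both ligands, and 94, 92, 110 and 97 without the untreated, poly(I:C), R848 and combined libraries of experiment 2. At 0.5 and 1 h limma called 0 genes, with 131 and 93 at an unadjusted p under 0.05. The F-test over all times gave 837 genes, of which 697 were never called higher under a ligand and 582 had a sum at the floor at 1 or more times. It gave 1584 without any of the 4 libraries at 2 h of experiment 2. On the log2 scale, a test of whether the ligands' effects multiply called 416 genes (270 with a positive and 267 with a negative departure at 1 or more times). Its share of positive departures was 51.2% at 8 h and 49.9% at 12 h, against 26.9% and 60.3% with median centring. It called 822 genes with the experiment as a block and 1097 without the 2 h library of both ligands of experiment 2.

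**Figure D4:**
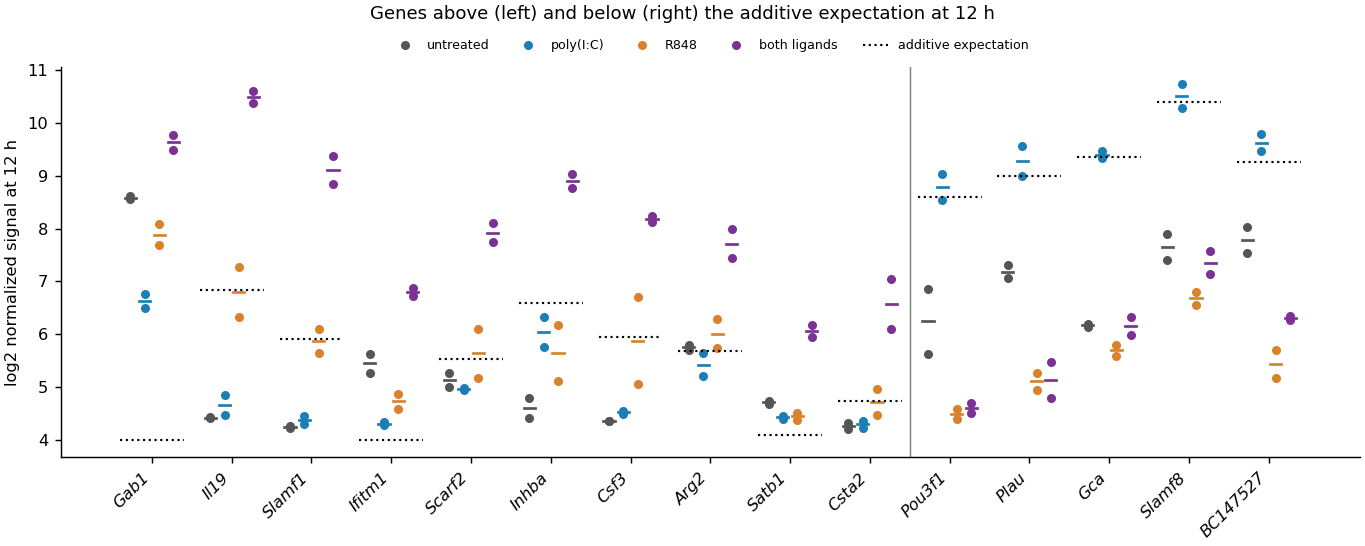
Log2 normalized signal at 12 h of the 10 genes furthest above and the 5 furthest below additivity among those called, in untreated cells and under poly(I:C), R848 and both ligands; points are single libraries, bars their means, and dotted lines the sum of the separate increases over untreated. Il19 under both ligands (10.49) lies above its line, and Slamf8 (7.36) lies below.

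Further lists fixed beforehand passed the test under 1 or more ligands. At 12 h of poly(I:C), immediate-early genes (7 of 15 rose; median 1.12, adjusted p = 1.7e-06, and 0.012 with an estimated correlation), co-stimulation genes (4 of 9 rose; 0.91, 9.6e-07 and 0.011), genes of the TLR pathway (4 of 22 rose; 0.36, 0.0041 and 0.012), cell death genes (6 of 13 rose and 1 fell; 0.83, 5.9e-06 and 0.00038) and SOCS and DUSP feedback genes (7 of 11 rose; 1.52, 8.5e-06 and 0.02) passed. Among them were Cd40 (7.99-fold higher), Fas, a death receptor gene (2.30 ± 0.20), and Irak2 (1.72 ± 0.15). Glycolysis genes passed with a median of 0.77 and 3 of 12 higher (adjusted p = 0.00016, and adjusted p = 0.059 with an estimated correlation). At 12 h of R848, immediate-early genes (0.80, adjusted p = 0.012, and 0.18 with an estimated correlation) and feedback genes (0.86, 0.0023 and 0.11) passed, the former not with the experiment as a block. Under both ligands immediate-early genes (0.90, 0.00075, and 0.072 with an estimated correlation), co-stimulation genes (1.28, 0.00097 and 0.081) and feedback genes (1.57, or 1.45 at the bounds, 7.4e-05 and 0.039) passed. Cd86, a co-stimulatory ligand gene, fell under R848 (-2.53 ± 0.20) and both ligands (-1.17 ± 0.20) and differed by 0.91 ± 0.20 under poly(I:C), less than 2-fold.

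Lists that did not pass the test at 12 h are given in the order poly(I:C), R848, both ligands. Median differences were 0.33, -0.51 and 0.14 for IRF and STAT factors (adjusted p = 0.19, 0.19 and 0.98), -0.43, -0.26 and -0.35 for cholesterol synthesis (0.19, 0.56 and 0.24), -0.36, -0.63 and -0.54 for cholesterol efflux (0.72, 0.29 and 0.39; -0.08, -0.14 and -0.26 at the bounds) and -0.29, 0.00 and -0.34 for the TCA cycle and oxidative phosphorylation (0.18, 0.93 and 0.24). They were -0.40, -0.24 and -0.23 for the cell cycle (0.33, 0.3 and 0.68; -0.06 at the bounds under poly(I:C)), 0.34, -0.05 and 0.16 for stress responses (0.17, 0.19 and 0.13), -0.36, -0.02 and -0.30 for ribosomal proteins (0.055, 0.89 and 0.38) and 0.14, 0.31 and 0.22 for housekeeping genes (0.94, 0.64 and 0.86). Ribosomal protein genes passed under poly(I:C) with the authors' scaling or without the untreated 12 h library of experiment 1. For poly(I:C) alone MHC class II (-0.48, adjusted p = 0.21) and lysosome genes (-0.31, 0.17) did not pass. For R848 alone interferon genes (0.12, 0.93), interferon-induced GTPases (-0.36, 0.94), MHC class I (-0.11, 0.49), co-stimulation (1.53, or 0.90 at the bounds, 0.1), the TLR pathway (0.10, 0.85) and cell death (0.07, 0.51) did not. For both ligands interferon genes (0.63, or 0.26 at the bounds, 0.14), MHC class I (0.24, 0.41), the TLR pathway (0.16, 0.39) and cell death (0.49, 0.068) did not.

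Of the marker lists for other cell types, neutrophil markers alone had 3 or more members measured (7 of 12). Their medians at 12 h were 0.02, 0.20 and 1.26 under poly(I:C), R848 and both ligands (adjusted p = 0.37, 0.15 and 0.12). Members moved both ways under both ligands: S100a8 rose by 3.68 ± 0.24 and Mmp9 by 1.61 ± 0.25, Camp was at least 11.5-fold higher, and S100a9, the partner of S100a8 in calprotectin, fell (-1.67 ± 0.28). T cell, dendritic and megakaryocyte markers had 2 members measured each, B cell, NK cell and stromal markers 1, and erythroid and mast cell or basophil markers 0, so these lists were not tested.

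**Figure D5:**
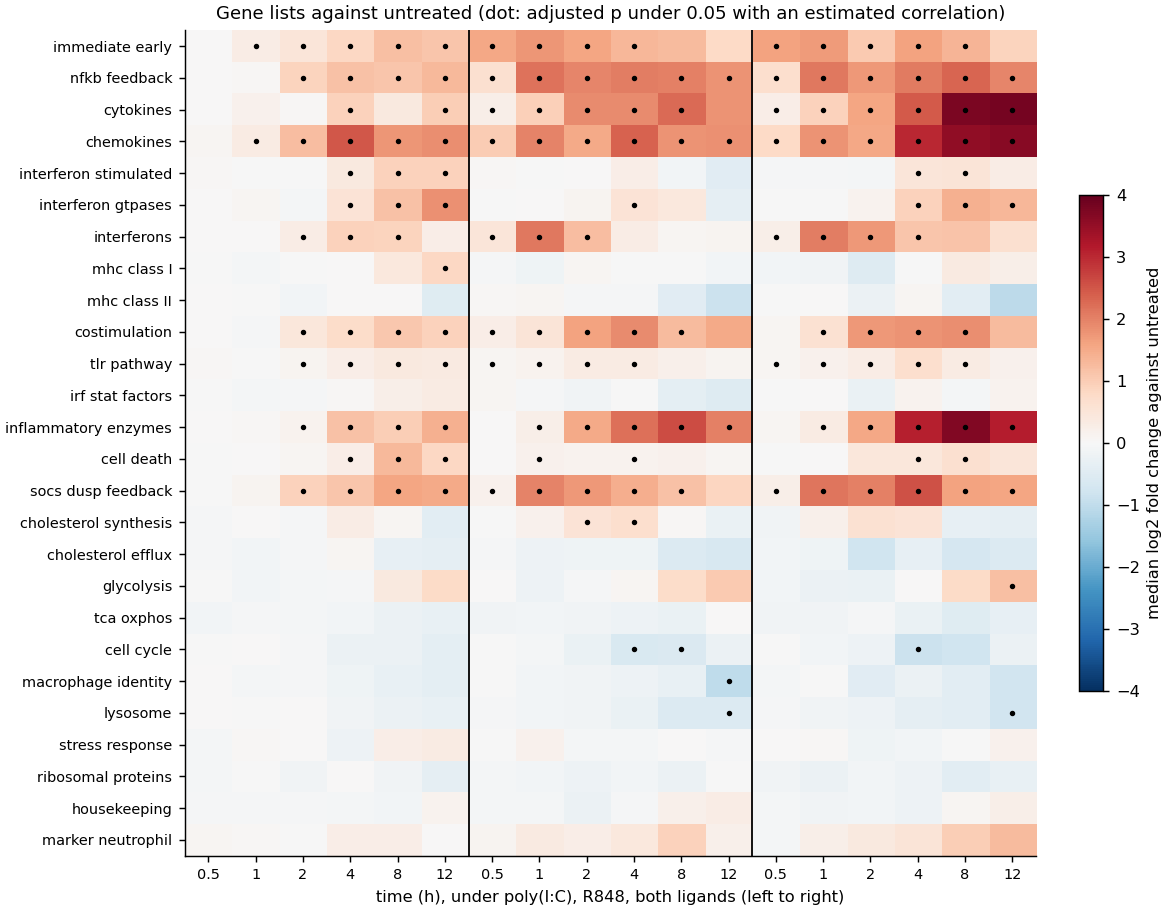
Median log2 difference from untreated of each gene list (y axis) at each time and treatment (x axis, time in h); colour gives the median, and dots mark tests with an adjusted p under 0.05 with an estimated correlation. Cytokine genes reach 3.82 at 12 h of both ligands, and interferon-stimulated genes read 0.92 under poly(I:C) and -0.46 under R848 at 12 h.

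Responses at 12 h were compared with those at 2 h. Under poly(I:C), Hdc (3.97 ± 0.38, adjusted p = 4e-08), Plpp1, a lipid phosphatase gene (3.85 ± 0.32), and AA467197 (4.10 ± 0.36) were further above untreated at 12 h than at 2 h, as were Tmem178 (3.97 ± 0.68) and Ptges (at least 20.5-fold). In the other direction, St6gal1 (-4.38 ± 0.26), Slc46a3 (-3.83 ± 0.39), Cxcr4 (-3.13 ± 0.44) and Hpgd, a prostaglandin-degrading enzyme gene (at least 4.32-fold), were further below. Under R848, Plpp1 (5.46 ± 0.32), Trem3, an activating receptor gene (4.97 ± 0.28), Lcn2 (4.74 ± 0.61) and Upp1 (at least 8.26-fold) gained. Slc46a3 (-5.69 ± 0.39), Zfp36l1 (-4.93 ± 0.33), Cish, a feedback inhibitor of STAT5 (at least 26-fold), the activation marker Cd83 (-4.43 ± 0.54) and Adssl1 (-4.26 ± 0.24) lost. Under both ligands Dgat2, a triglyceride synthesis gene (at least 20.9-fold), Hp, the haptoglobin gene (4.92 ± 0.42), and Lcn2 (5.07 ± 0.61) gained. Cyp27a1, a sterol hydroxylase gene (-4.77 ± 0.44), Ccnd1 (-4.81 ± 0.41) and Zdhhc14 (-4.50 ± 0.26) lost. These differences span 4 groups, and those with a group at background in both libraries are given as bounds.

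The difference between 12 h and 2 h passed for 484 genes under poly(I:C) (233 higher, 251 lower), 952 under R848 (526, 426) and 1225 under both ligands (517, 708). With the experiment as a block the first 2 counts were 777 and 1441. Without the 2 h library of both ligands of experiment 2 the last was 2204 (982, 1222). The lower count for poly(I:C) was 165 without the untreated 2 h library of experiment 2, and the higher count for R848 was 322 and 830 without the R848 12 h library of experiments 1 and 2. The share of higher genes under both ligands was 42.2%, against 64.7% with median centring. Under R848 it was 55.3%, against 65.3% with median centring and 45.5% after quantile normalization, and under poly(I:C) 48.1%, against 54.7% and 55.1%.

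The change from 2 to 12 h was also compared between treatments. Against poly(I:C), both ligands gained Il19 (at least 10.4-fold, adjusted p = 1.9e-08), Adgre5, the CD97 gene (4.08 ± 0.58), and Lcn2 (3.95 ± 0.61). They lost Ccnd1 (-5.56 ± 0.41), Vcam1, an adhesion molecule gene (-5.11 ± 0.35), Hspa1a, a heat shock gene (-4.73 ± 0.63), Il15ra (-4.44 ± 0.45) and Slco4a1 (-4.29 ± 0.44). That comparison called 847 genes (369 higher, 478 lower), 1393 with the experiment as a block and 1868 (916, 952) without the 2 h library of both ligands of experiment 2. Without the poly(I:C) 12 h library of experiment 2, 240 genes were higher. Its share of higher genes was 43.6%, against 71% with median centring. Against R848, both ligands lost Sesn1 (-2.22 ± 0.32, adjusted p = 0.00022) and Kcnk13, a potassium channel gene (-2.26 ± 0.38). Both calls ended with only the libraries of 2 and 12 h in the fit, where limma called 0 genes, with 1144 at an unadjusted p under 0.05. In the fit to all libraries the comparison called 534 genes (328 higher, 206 lower), 1475 with the experiment as a block. That count rested on the libraries that stood apart. It was 67 without the 3 of them, 38 of these among the 534, and without any 1 of the 8 libraries compared it lay between 51 and 2503 (38 to 1007 higher, 13 to 1496 lower). Its share of higher genes was 61.4%, against 84.8% after quantile normalization. The largest rises, Slc28a2, Gnas, Gm8909, Mx1 and Ppp2r1a (5.77 to 6.00), were 0.80, 0.19, 0.60, 0.61 and 0.64 without the 3 libraries and no longer called.

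Untreated cells also differed between the ends of the course. Their 0.5 h and 12 h libraries lie on different slides in both experiments, so time and slide cannot be told apart here. From 0.5 to 12 h Hpgd rose by 2.14 ± 0.29 (adjusted p = 2.1e-05) and St6gal1 by 1.39 ± 0.18, and Hmgn3 (-2.49 ± 0.16, adjusted p = 3.9e-11), Cxcl10 (-2.65 ± 0.20), AA467197 (-2.84 ± 0.25) and Mmp13, a collagenase gene (-2.48 ± 0.33), fell. Gbp5 (-2.62 ± 0.63) lost its call without the untreated library at 0.5 h of experiment 2 (-2.12) or either at 12 h (-2.43 and -2.82). In all 87 genes differed (13 higher, 74 lower), 135 with the experiment as a block and 56 without the 0.5 h library of experiment 2, which left 48 lower. Without either 0.5 h library 8 were higher and without the 12 h library of experiment 1 it was 7. The share of higher genes was 14.9%, against 28% with median centring. Interferon-stimulated genes had a median of -0.56 in this comparison, with 3 of 37 lower, and interferon-induced GTPase genes -1.15, with 4 of 10 lower. List tests were not run for it.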

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

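The tests of exchanged treatments, the comparison with the larger single response and the test of genes lowered by R848 were chosen after the results were seen. The test of the R848 library that stands apart was devised after that library had been seen, with its bounds written before its result. The others in this part were planned.

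The response differed between 2 h and 12 h by a direct test for 484 genes under poly(I:C), 952 under R848 and 1225 under both ligands, and the change from 2 to 12 h differed between both ligands and poly(I:C) for 847 genes and between both ligands and R848 for 534. Part of the 952, 1225 and 847 genes lost their calls without the libraries that stood apart, while other genes gained them. The count of 534 rested on those libraries. With only the libraries of 2 h and 12 h in the fit, limma called 0 genes there, with 1144 at an unadjusted p under 0.05. In opposite directions at the 2 times were called 11 genes under R848, 16 under both ligands and 0 under poly(I:C), where limma called 34 genes at 2 h. Under R848, Cd83 went from 3.17 at 2 h to -1.26 at 12 h, P2ry13, a nucleotide receptor gene, from 1.86 to -1.86, Il15 from 1.25 to -1.92 and Cdkn1a, a cell cycle inhibitor gene, from 1.35 to -1.52. Cdca7 (from -1.41 to 1.41), Trmt61a (from -1.24 to 1.77), Gsdme and A130010J15Rik went the other way under R848. The 16 genes under both ligands went each way, and their calls include the 2 h library that stood apart. The 12 h calls of the 11 genes under R848 likewise include the R848 library that stood apart, which lost signal at 239 genes and gained it at 2. These genes were chosen after their values were seen, and the 12 h call of Cd83 ended at -1.02 without the R848 and at -1.06 without the untreated 12 h library of experiment 2. Departures from multiplying effects of the ligands passed for 416 genes. Outside the named genes, 599 probes with no single gene symbol were above background, of which 41 were higher and 67 lower under both ligands than in untreated cells at 12 h (18%, against 22.9% of named genes).

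Chance alone is argued against as the source of the counts in the 6 comparisons of treatments over all times. It is not excluded, since 1 of 64 is the smallest share that the splits below can give. Exchanging the 2 treatments in 1 experiment at any set of times gives 64 splits that keep the pairs, and in each comparison 1 of 64, the real one, gave as many genes: 997 for poly(I:C) against untreated, with 992 in the highest other split and a median of 31 over the others, 2206 (2189 and 356) for R848, 2679 (2666 and 382) for both ligands, 1603 (1592 and 300) for both against poly(I:C), 188 (185 and 0) for both against R848 and 1465 (1445 and 242) for R848 against poly(I:C). The highest other splits exchange treatments at early times, where few genes are called, and keep the rest of the real grouping. In 100 random draws, which can also exchange both experiments of a time and so leave the F-test as it was, 3, 1, 1, 2, 2 and 1 draws gave as many.

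Genes whose signal under both ligands lay below the sum numbered 194 at 12 h. Saturation of the arrays is argued against, since 2.1% of them came within 1 log2 unit of the highest signal of an array. The 392 genes below the sum in experiment 1 had a median departure of -0.70 in experiment 2, against -0.24 for all genes raised by a ligand, so the departures repeated. As a test of the R848 library that stands apart this could hardly fail, since a lost R848 signal lowers the sum and moves genes above it. That library lost signal at 239 genes and gained it at 2, so its loss bears on genes above the sum and on those not called higher under R848. Genes below the sum were then chosen in 1 experiment and read in the other. Which ligand raised them was called from both experiments for poly(I:C) and from experiment 2 alone for R848, so the reading is not fully held out. A response capped at the larger single response stays open for genes raised by each ligand (median ratio of both ligands to the larger single one -0.24, quartiles -0.61 to 0.07) and by R848 alone (-0.24, quartiles -0.61 to 0.06). For genes raised by poly(I:C) alone the ratio was lower, at -1.07 (quartiles -1.64 to -0.67). Choosing them by a high poly(I:C) signal lowers this ratio by an amount not measured, so how far it argues against a cap is not settled. Whether R848 itself lowers the genes that poly(I:C) alone raises stays open. Read in the same way, their median change under R848 was -0.02 and members went both ways (quartiles -0.68 to 0.53), with genes called higher under R848 left out by the choice. Open too, as a hypothesis found on the same data, is that R848 may limit the response to poly(I:C). The 202 genes higher at 12 h under poly(I:C) and not R848 had a median ratio of -0.81. They were chosen without the combination but by a high poly(I:C) signal in the same libraries, which lowers this ratio by an amount not measured. The median was -0.24 for the 511 higher under R848 and not poly(I:C), chosen in the same way by R848. For the 229 higher under each ligand it was 0.14 (quartiles -0.17 to 0.47), and 52 of them were called below the sum. Their ratio cannot decide, since where R848 gives the larger signal, a lost poly(I:C) response would only make both ligands equal R848. Timing and feedback between the pathways were not tested.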

How the results depend on the processing

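The alternatives without the 3 libraries that stand apart and with array quality weights were chosen after seeing the data; the others were planned. For counts that moved by over 1.5 times the cause was not tested, except where fewer genes or libraries enter by construction. The number of list tests that passed (209) stayed between 156 and 230 in every alternative run, and no list test passed in the opposite direction. Of 1075 values of named and indicator genes, 1 reversed: Cd40, at -0.07 from the sum at 12 h, was at 0.74 (adjusted p = 0.00605) against the larger single ligand, the 1 alternative in which it passed. Median centring ended 68 gene calls and added 7, quantile normalization ended 62 and added 6, the authors' normalized values ended 59 and added 6, and the experiment as a block ended 2 and added 16. With each library left out in turn, 99 of 916 values of named genes lost their call, counted per gene, comparison and library left out.

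The counts follow in the order poly(I:C), R848 and both against untreated, both against poly(I:C), both against R848, R848 against poly(I:C), the interaction, 12 h against 2 h under poly(I:C), R848 and both, the change from 2 to 12 h of both against poly(I:C) and against R848, and untreated drift. Quantile normalization of the raw signal gave 514, 1067, 1342, 710, 89, 694, 263, 265, 470, 659, 421, 230 and 37. The authors' normalized values gave 554, 1125, 1439, 763, 92, 730 (the interaction moved by less), 296, 510, 704, 449, 243 and 39. Median centring gave 76 (both against R848), 185 (interaction), 159, 487, 708, 520, 55 and 25. Testing only genes above background in all 48 libraries gave 1391 and 1675 for R848 and both, 972, 115 and 914 between treatments, 789 for 12 h against 2 h under both, and 541 and 208 for the changes. No minimum fold gave 1549 for poly(I:C), 2495, 342 and 2358 between treatments and 168 for drift. An adjusted p under 0.01 gave 275 (interaction), 492 (additivity), 588 (R848 at 12 h against 2 h), 553 and 71. Only the libraries of the times compared gave 208, 476 and 679 for 12 h against 2 h, 434 and 0 for the changes. Beside that 0, limma had 1144 genes at an unadjusted p under 0.05. Every probe gave 948 for the change against R848, and the larger single ligand 1716 for additivity.

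The experiment as a replicate block gave 338 (both against R848), 822 (interaction), 777 and 1441 (12 h against 2 h under poly(I:C) and R848), 1393 and 1475 (changes) and 135 (drift), and left each other count within 1.5 times. A slide block gave 342, 836, 784, 1441, 1405, 1490 and 138, and slide as a random block 344, 801, 761, 1430, 1390 and 1447. The replicate block with array quality weights gave 436, 768, 889, 1441, 141 (change against R848) and 157, and the block without the 3 libraries 290, 925, 881, 150 (change against R848) and 156. Leaving out the 3 libraries without a block moved 1 count by over 1.5 times, the change against R848, to 67. Of the genes called, 925 of 997, 2044 of 2206 and 2562 of 2679 in the comparisons with untreated were called without them too, as were 150 of 188 for both against R848 and 87 of 87 for drift. A smaller part of the calls held without the 3 libraries for 12 h against 2 h under R848 and both ligands and for the change against poly(I:C). Their totals stayed within 1.5 times because other genes were called instead. Under the replicate block the list tests of immediate-early genes under R848 and of interferon genes under poly(I:C) at 12 h ended. At 8 h those of lysosome genes passed under R848 and both ligands. Other changed list calls lay at the remaining times and in additivity, 213 passing in all.

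Without 1 library each, the counts ranged from 905 to 1149, 2098 to 2472, 2582 to 3472, 1460 to 2574, 151 to 1238, 1368 to 1889, 328 to 1097, 351 to 556, 751 to 1411, 995 to 2204, 636 to 1868, 51 to 2503 and 56 to 99 in the same order, from 628 to 1584 for additivity and from 199 to 214 for lists; the remaining library of a group is then assumed to vary like the others. The median of all genes moved by over 0.1 log2 units with median centring in these comparisons of treated with untreated cells: from -0.03 to -0.14 and from -0.07 to -0.18 at 2 and 12 h of poly(I:C), from -0.11 to -0.27 at 2 h of R848, and from -0.02 to -0.31, -0.13 to -0.28 and -0.09 to -0.28 at 2, 4 and 8 h of both. The same shift ran from -0.05 to 0.26 for 12 h against 2 h under both, and from -0.01 to 0.30 and -0.24 to -0.04 for the changes against poly(I:C) and R848. Slide as a random block and every probe were not run for lists, and only the libraries of the times compared gives no F-test over all times. Signal over background limits the genes seen: 1411 of the 19692 probes in the authors' table were at background in every library at a detection p of 0.05.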

Other observations

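The tests of the treatment in experiment 2, across the slide and of R848 beside poly(I:C) were chosen after the results were seen, the others in this part were written before, and the genes named here were chosen from the fixed lists after their values were seen.

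Single members of the TLR pathway list changed in either direction at 12 h of R848 and both ligands, where the list as a whole did not pass. Tlr13, a receptor for bacterial ribosomal RNA, fell under R848 (-2.18 ± 0.43) and both ligands (-2.73 ± 0.43), and Tlr4, the lipopolysaccharide receptor gene, fell too (-2.08 ± 0.33 and -2.32 ± 0.33). The adaptor genes Ticam2 (2.06 ± 0.23 and 1.45 ± 0.23) and Tirap (1.96 ± 0.30 and 1.54 ± 0.30) and the kinase gene Irak2 (2.30 ± 0.15 and 2.15 ± 0.15) rose in the same comparisons. Under poly(I:C) Tlr13 (-0.29), Tlr4 (-0.26), Ticam2 (0.12) and Tirap (0.42) did not pass the test, while Irak2 rose there too. The direct comparison of the ligands is not given for the genes of this part.

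Single metabolic and stress genes changed inside lists that did not pass as a whole. Slc7a11, the cystine importer gene, rose by 2.22 ± 0.30, 4.42 ± 0.30 and 4.75 ± 0.30 at 12 h of poly(I:C), R848 and both ligands, and Hmox1, which degrades heme, by 1.31 ± 0.21, 1.31 ± 0.21 and 1.28 ± 0.21. Hspa1a was at least 6.76-fold higher under poly(I:C) and at least 2.35-fold higher under both ligands. Idh1, the cytosolic isocitrate dehydrogenase gene, fell under R848 (-2.72 ± 0.42) and both ligands (-3.57 ± 0.42), as did Bcl2l11, a pro-apoptotic gene (-2.65 ± 0.43 and -3.29 ± 0.43).

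Probe signal was lost in the 3 libraries of experiment 1 that stand apart. A treatment effect common to both experiments is argued against: genes chosen by their loss in the other 2 libraries had a median change against untreated of -1.69 in experiment 1 and of 0.04 in experiment 2 (quartiles -0.38 to 0.52). A fault of the whole slide is argued against by a median deviation of the lost genes of 0.03 on the other arrays of the slides. These other arrays leave out the 3 libraries themselves, of which R848 at 12 h and poly(I:C) at 8 h share a slide. A fault of part of a slide was not tested. Loss at single probes rather than of whole transcripts is consistent with a median deviation of -0.56 at 174 other probes of the same genes, against -2.87 at the lost probes, but the quartiles of these other probes, -2.44 to 0.37, leave part of the genes open. The loss repeated between libraries, with 203 genes shared by the first and second where chance gives 15.2, and no cause at the bench was tested.

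Interferon-stimulated genes had a median of -0.46 at 12 h of R848. The R848 library that stands apart is argued against as the whole source, since the list's median was -0.37 in experiment 1 and -0.39 in experiment 2 alone. Without that library it was -0.27 and the call ended, but that fit sets R848 of experiment 2 against untreated cells of both experiments. The -0.27 therefore also carries the difference between the experiments and does not settle what part that library adds. Also argued against is a fall of all genes of that brightness, since the list lay at percentile 0.83 of random lists of matched level, whose median was -0.08, and that percentile is close to the bound of 1 set beforehand. An effect of R848 that also acts beside poly(I:C) is consistent with a median of -0.64 for both ligands against poly(I:C). The pattern remains a hypothesis, since the list's call did not hold in every alternative and the same list had a median of -0.56 in untreated cells at 12 h against 0.5 h, where the times lie on different slides and no list test was run.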
